A study of Mus musculus with 8 samples.

How the data were processed

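RNA from the livers of 8 female calorie-restricted Ames dwarf mice was measured on Affymetrix U74Av2 arrays, 1 array per mouse, per the labels. The labels give 24 to 26 months as the age at death, state that the tissue was frozen on dry ice and kept in liquid nitrogen, and name a Hewlett-Packard GeneArray scanner. The deposited table holds 1 intensity per probe set and array, on a linear scale with no value at or below 0. The mean intensity without the lowest and highest 2% of probe sets came to about the same number on every array (a spread of 0.0140% over the 8 arrays), so the deposited intensities count as already scaled between arrays. Software that summarized the probes of a set into that intensity is not given in the sources used here. All 8 columns matched a sample, and 0 columns were left without one.

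Several choices were made before the data were examined: the tests, the gene lists, the pairs of lists, the rule for named genes and most of the alternatives. Intensities were used as deposited, raised to a floor of 37.2 (the 25th percentile of all values) and converted to log2. Probe sets with a mean of at least 165.2 over the 8 arrays (the median of all values) were tested, and control probe sets (66 in the table) were left out. Of 50120 tested values, 67 (0.134%) lay at the floor. The table of probe set names gave 1 gene symbol for 10833 probe sets, several for 396 and none for 1193, and probe sets with several were not named. Of the symbols, 10817 were found by their Entrez identifiers in a reference list of mouse genes, and 0 changed. That list holds some older symbols, such as G6pc for G6pc1 and Arntl for Bmal1, so the symbols need not be the newest. A gene with several tested probe sets was represented by the one with the highest mean. That left 6265 probe sets and 4869 genes, and 622 tested probe sets without a named gene. Probe sets whose names end in f or s share probes with related transcripts, so the genes they name (Saa2, Mup3, Cyp2c38, Rpl41, Cry1, Plk1 and others) are uncertain within their families.

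With 1 group there is no contrast between groups, and each comparison is between mice. Spread was tested for each probe set by the ratio of its variance of log2 values over the 8 mice (7 degrees of freedom) to the variance expected at its brightness, with the trend and the prior degrees of freedom (3.80) estimated robustly by limma's squeezeVar, by a one-sided F test with Benjamini-Hochberg adjustment at 0.05. The 36 fixed lists held 628 genes, of which 480 had a named probe set. A list's score in a mouse is the mean over its tested members of the log2 intensity minus the gene's mean over the 8 mice. The 26 lists with at least 5 tested genes were tested for over-representation among varying genes (one-sided Fisher's exact test) and for members that vary together. The latter compares the mean correlation between members over the 8 mice with that of 10000 random lists of the same size and brightness (10 bins), one-sided, and the smallest p those lists can give is 0.0001. The other 10 lists are described only, though their scores enter some of the pairs and the later comparisons with the interferon score. The scores of 16 pairs of lists were compared by Pearson's r and Spearman's rho with an exact two-sided permutation test over the 40320 pairings of the mice, and r was taken again without the 2 mice farthest from the median of the first score. Adjusted p-values are Benjamini-Hochberg values over the lists or over the pairs. For each list the F test p-values were also adjusted over its tested members alone. That adjustment was not in the plan, takes no account of the number of lists, and counts members that vary together as separate genes. Its counts are therefore descriptive.

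The rule for named genes took the 12 genes with the largest F ratio past the threshold in which no mouse stands apart, the 6 in which 1 mouse does, up to 3 members of each list past the threshold or else the member with the highest mean, and all measured genes of a label check list. Because no gene passed, the rule left the member of each list with the highest mean and the label check genes. Every other gene named in the text was chosen after its values were seen, most by the same rule applied to a chi-square test of the variance against the brightness trend alone, and the others for their slopes on the interferon score. A mouse was taken to stand apart where its gap to the nearest other mouse exceeded 0.526 of the range, Dixon's critical value for 8 values, which chance exceeds about once in 20.

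The tests were tried on simulated data. With variances spread as estimated here, the F test found 0% of 200 planted probe sets with an SD 2, 4 or 8 times the trend among 6265, and with no such spread it found 40.0%, 95.8% and 99.7%. The chi-square test marked 18.8% of the unchanged probe sets in the first setting and 0.122% in the second. The list test called 10 of 10 planted lists and 0 of 10 others among 4869 genes, with a planted factor as large as the noise of a gene. The permutation test gave p under 0.05 in 4.5% of 200 unrelated pairs of scores and in 98.5% of 200 planted pairs. The planted pairs were strongly related, so their share does not give the power for weaker relations. The unrelated pairs had no pattern common to the arrays, so their share does not give the error rate for scores that have one.

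Alternatives were quantile normalization, scaling each array to a common median, lower and higher floors, no filter and a stricter filter (70th percentile), removal of the first principal component, each mouse left out in turn, no trend or no robust estimation in the F test, the mean of all probe sets of a gene, and other list scores. Scaling to a common median moved the values of mouse 5 by 0.18 on the log2 scale, and those of mouse 8, the next in size, by -0.10. Added after seeing the data were the chi-square test, a run without family probe sets (names ending in f, s or i left out), and a block for 2 sets of arrays. The labels give no batch, but the 9 hybridization control probe sets, RNAs added in known amounts, split the arrays into mice 1 to 4 and mice 5 to 8. Each set of 4 mice is too small for a correlation of its own, so the value with the set as a block is given. The number of arrays limits the precision, since each mouse was measured once. Analyses used R 4.3.3 with limma 3.58.1, and the figures were drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.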

Results

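Gene expression was measured in the livers of 8 female Ames dwarf mice, each on its own Affymetrix U74Av2 array, a short oligonucleotide array of mouse transcripts. Ames dwarf mice (df/df) lack the pituitary cells that make growth hormone, prolactin and thyroid stimulating hormone, and they are long-lived. All 8 mice had received 30% less food than dwarf mice with free access to it, and they were killed at 24 to 26 months of age. They form 1 group. Dwarf mice with free access to food and mice without the mutation were not analysed here, so the data carry no measure of the effect of the diet or of the mutation, and the comparisons are between individual mice. The table gave an intensity for 12488 probe sets on each array, and 6265 of them, for 4869 named genes, were bright enough to test.

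Genes that bear on the labels were read first. Xist, the noncoding RNA that silences an X chromosome in female cells, had an intensity of 687 ± 421 (SD, n = 8), from 95.8 in mouse 5 to 1572 in mouse 8. The Y-linked genes Eif2s3y, Kdm5d and Uty averaged 14.9 ± 8.05, 5.48 ± 2.08 and 21.7 ± 20.5, each mean below the floor of 37.2 set for this table, but Uty read 70 in mouse 1, above that floor. Igf1, the growth factor whose transcription in liver depends on growth hormone, averaged 1238 ± 240 on the brighter of its 2 probe sets and 534 ± 143 on the other. Igfals, another growth hormone target that binds IGF1 in serum, averaged 62.9 ± 9.05 on the brighter of its probe sets and was too dim to test. The growth hormone receptor gene Ghr averaged 3872 ± 720 on the brighter of its 2 probe sets and 1593 ± 369 on the other. Albumin (Alb), the main secreted protein of hepatocytes, averaged 29253 ± 4809, and its highest value was 1.51 times its lowest.

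Among the named genes, the widest ranges between livers were in genes of inflammation and antigen presentation. Ubd, a ubiquitin-like protein induced by interferon and tumour necrosis factor, read 7460 in mouse 8, 7065 in mouse 6 and 3662 in mouse 3, against 91.8 in mouse 2, 43.7 in mouse 5 and a value under the floor in mouse 7. Saa3, an acute phase serum amyloid, ranged 96.8-fold, from 124 in mouse 7 to 12035 in mouse 8, and Lcn2, a siderophore-binding protein, ranged 54.5-fold, from 180 in mouse 7 to 9797 in mouse 8. The guanylate-binding GTPases Gbp3 and Gbp2 ranged 39.8-fold and 35.1-fold, with the highest values in mouse 6 (6327 and 4554). The chemokine genes Ccl2 (under the floor in mouse 7 and 2740 in mouse 8) and Cxcl9 (78.2 in mouse 5 to 2502 in mouse 8) also ranged widely. The median gene had an SD of 0.23 on the log2 scale between mice, and the 90th percentile of genes was 0.50.

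No gene passed the test of spread taken singly. In the F test with limma's moderated variances, 0 of 6265 probe sets had an adjusted p under 0.05 (the lowest was 0.265), and 400 (6.38%) had an unadjusted p under 0.05. The chi-square test against the brightness trend alone, added after the data were seen, marked 1147 probe sets (18.3%) and 793 of 4869 genes (16.3%). That count is descriptive, because in simulated data with the estimated spread of variances the test marked 18.8% of unchanged probe sets. The F test found 0% of the planted probe sets there, so in that setting its count of 0 excludes no difference between mice. Where a gene had 2 tested probe sets of different sequences, their correlation over the mice had a median of 0.381 for 112 genes marked by the chi-square test and 0.188 for 478 others, and it exceeded 0.5 in 41.1% and 28.2% of them. Among the 26 lists tested, 0 were over-represented among genes passing the F test, which follows from its count, and 7 were among genes marked by the chi-square test. Fisher's exact test, used here, treats the members of a list as independent, and members that vary together are not.

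**Figure D1:**
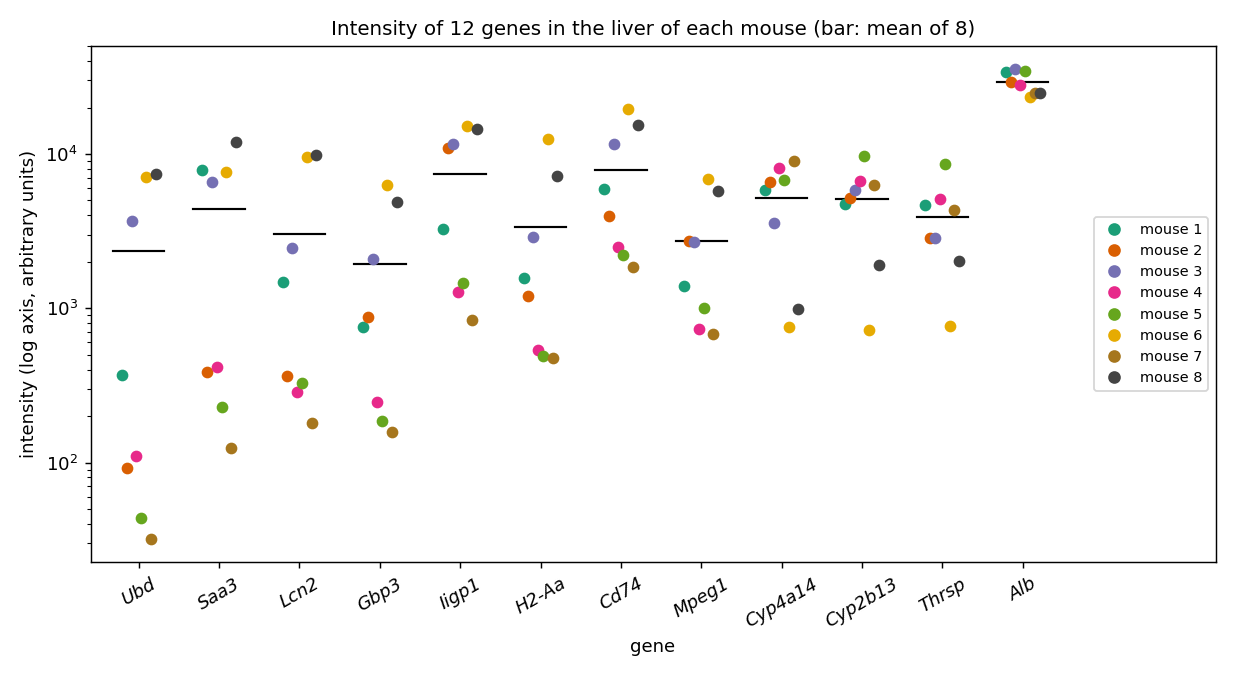
Intensity (log axis, arbitrary units) of 12 genes in each of the 8 mice, 1 coloured point per mouse, with a bar at the mean of the 8; the panel's genes were chosen after their values were seen. Ubd ranged from under the floor in mouse 7 to 7460 in mouse 8, Cyp4a14 from 761 in mouse 6 to 8973 in mouse 7, and Alb from 23417 to 35343.

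Whole groups of genes varied together between the mice. In 15 of the 26 lists tested the members correlated over the 8 mice more than random lists of like brightness did at an adjusted p under 0.05 (17 lists at an unadjusted p, with 1.3 expected by chance). The 17 tested interferon response genes had a mean correlation of 0.926 between members against a median of -0.0047 in random lists (p = 0.0001, the smallest the random lists can give, adjusted p = 0.000371). Their score was -0.12, 0.15, 0.68, -1.43, -1.34, 2.0, -1.43 and 1.49 in mice 1 to 8, a range of 3.44 on the log2 scale. Iigp1, an immunity-related GTPase, read 839 in mouse 7 and 15220 in mouse 6 (18.1-fold), its relative Igtp 240 in mouse 7 and 6152 in mouse 6, and the immunoproteasome subunit Psmb8 332 in mouse 7 and 6130 in mouse 6. In the F test 0 of the 17 passed over all genes, 17 passed when adjusted over the list alone, and 17 had an unadjusted p under 0.05. The count over the list alone, here and for the lists below, is descriptive, because that adjustment was not planned and members vary together.

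MHC class II genes, which present antigen to helper T cells, had a mean correlation of 0.960 among 8 tested members (adjusted p = 0.000371) and a score from -1.39 in mouse 5 to 2.19 in mouse 6. H2-Aa averaged 3366 ± 4344 and ranged 26.3-fold, H2-Ab1 averaged 1122 ± 1240 and ranged 14.2-fold, and Cd74, the invariant chain, averaged 7898 ± 6828 and ranged from 1845 in mouse 7 to 19642 in mouse 6. With adjustment over the list alone 7 of the 8 passed the F test. The 14 macrophage markers had a mean correlation of 0.786 (adjusted p = 0.000371), with a score from -1.04 in mouse 7 to 1.84 in mouse 6, and 13 of them passed when adjusted over the list alone. Mpeg1, a macrophage perforin, ranged 10.1-fold from 683 in mouse 7 to 6915 in mouse 6, Lyz2 (lysozyme) 17.6-fold and the complement gene C1qa 15.2-fold. Of the T and NK cell list 3 genes were bright enough, too few to test. Among them Ccl5 lay at the floor in 4 mice and read 2069 in mouse 6, and Ltb read 48.9 in mouse 5 and 824 in mouse 8. Cd4, the third, differed in pattern, with 90.1 in mouse 4, 345 in mouse 3, 235 in mouse 6 and 259 in mouse 8. Of the 3 genes 2 passed the F test when adjusted over the list alone. Removal of the first principal component, which held 47.1% of the variance and along which mice 6 and 8 lay farthest to one side, ended the MHC class II call (mean correlation 0.114, adjusted p = 0.177), and the interferon response and macrophage lists still passed there at lower mean correlations (0.410 and 0.317). Mice 3, 6 and 8 lay at one end and mice 4, 5 and 7 at the other, both along that component and by interferon score. Its removal therefore takes out much of the interferon pattern itself, and a call lost there cannot tell whether that pattern is an artifact.

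Acute phase genes, whose products the liver secretes during inflammation, had a mean correlation of 0.250 among 23 tested members against a random median of 0.077 (adjusted p = 0.0487), with a score from -0.57 in mouse 7 to 0.64 in mouse 6. Adjusted over the list alone, 4 of the 23 passed the F test, and 7 had an unadjusted p under 0.05. Saa2, whose probe set shares probes with its relatives, ranged 16.0-fold from 980 in mouse 7 to 15643 in mouse 8. Haptoglobin (Hp), the brightest member, averaged 21529 ± 3384 and ranged 1.65-fold. Without mouse 5, 6 or 7 the call ended (adjusted p = 0.0676, 0.132 and 0.0957, at mean correlations of 0.223, 0.175 and 0.221), as it did with arrays scaled to a common median (0.964), with the stricter filter (0.0727, at a mean correlation of 0.250) and with the first component removed (0.515).

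Genes of fatty acid oxidation and of fatty acid synthesis varied together as well. The 20 tested genes of fatty acid oxidation had a mean correlation of 0.542 (adjusted p = 0.000371), with a score from -0.63 in mouse 6 to 0.30 in mouse 4. Cyp4a14, a fatty acid omega-hydroxylase controlled by PPAR alpha, read 761 in mouse 6, 990 in mouse 8 and 3572 in mouse 3, and between 5803 and 8973 in the other 5 mice. Ppara itself ranged 8.84-fold, from 344 in mouse 6 to 3038 in mouse 3, but it did not follow Cyp4a14 in every mouse (427 and 6735 in mouse 5, 1984 and 990 in mouse 8). The thioesterase Acot1 ranged 5.77-fold, from 79.0 in mouse 6 to 456 in mouse 7, while Acaa2, the brightest member, ranged 1.43-fold. Adjusted over the list alone 2 of the 20 passed the F test, and 4 had an unadjusted p under 0.05. Fatty acid synthesis genes (12 tested) had a mean correlation of 0.410 (adjusted p = 0.00491) and a score from -0.63 in mouse 6 to 0.29 in mouse 4, with 0 passing the F test over the list alone and 4 at an unadjusted p. Thrsp, a lipogenic gene induced by thyroid hormone and carbohydrate, read 769 in mouse 6 and 8548 in mouse 5 (11.1-fold), Me1 335 in mouse 6 and 1536 in mouse 2, and Elovl6 269 in mouse 6 and 957 in mouse 7. The oxidation call ended with the first component removed (adjusted p = 0.744), and the synthesis call with it (0.329), with arrays scaled to a common median (0.0636, though the mean correlation was higher there, 0.508) and without mouse 6 (0.0658).

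Sterol synthesis genes also varied together. Their 16 tested members had a mean correlation of 0.331 against a random median of -0.0054 (adjusted p = 0.000371), with the highest score in mouse 4 (0.38) and the lowest in mouse 6 (-0.27). Msmo1, a sterol demethylase, read 771 in mouse 6 and 4256 in mouse 4, squalene epoxidase (Sqle) 364 in mouse 7 and 1097 in mouse 8, and Sc5d 729 in mouse 6 and 2316 in mouse 4. None passed the F test over the list alone (0 of 16), and 3 had an unadjusted p under 0.05. The bile acid list (10 tested genes) had a mean correlation of 0.102 and did not pass (adjusted p = 0.207). Its Cyp7a1, the rate-limiting enzyme of bile acid synthesis, read 258 in mouse 6 and 1000 in mouse 1, and its brightest member Slc10a1, the bile acid uptake transporter, ranged 1.74-fold.

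**Figure D2:**
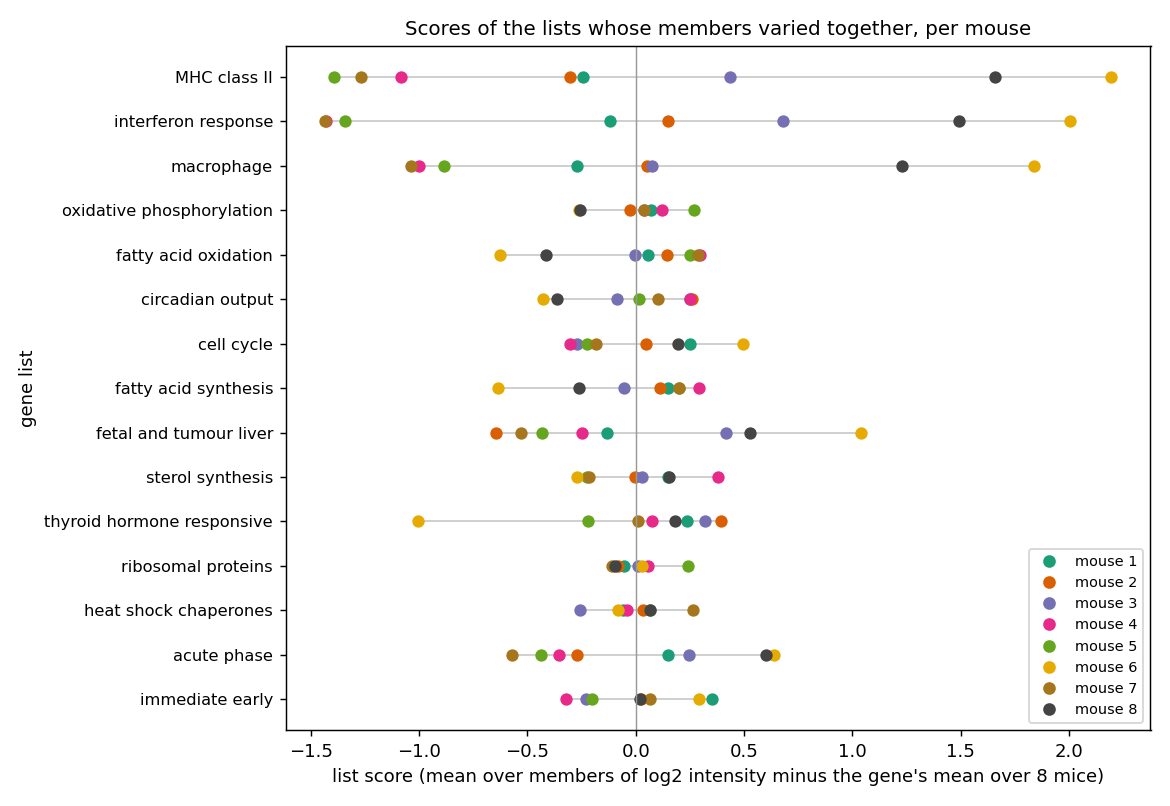
Scores of the 15 lists whose members varied together (mean over members of log2 intensity minus the gene's mean over the 8 mice), 1 coloured point per mouse, ordered by the mean correlation between members. The interferon response scores spread over 3.44 on the log2 scale and the ribosomal protein scores over 0.35.

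Lists tied to the hormones that Ames dwarf mice lack gave mixed results. The 7 tested growth hormone dependent genes did not vary together (mean correlation -0.062, adjusted p = 0.715), and their score stayed between -0.14 and 0.21. Egfr read 76.7 in mouse 4 and 448 in mouse 8, and the family probe set named for Mup3, a major urinary protein, read 3690 in mouse 6 and 10074 in mouse 5. The 6 thyroid hormone responsive genes had a mean correlation of 0.323 (adjusted p = 0.0303), with a score of -1.0 in mouse 6 and between -0.22 and 0.39 in the other 7 mice, and 4 of the 6 passed the F test over the list alone. That call ended without mouse 6 (adjusted p = 0.157), with arrays scaled to a common median (0.237, at a mean correlation of 0.321), with the stricter filter (0.163) and with family probe sets left out (0.292), and held with the first component removed (mean correlation 0.516). Of these 6 genes, Thrsp and Me1 are also in the fatty acid synthesis list, and Cyp7a1 is also in the bile acid list. These named members were lowest in mouse 6, but Bcl3, another member, was not. It read 774 in mouse 6, above its mean of 499, and ranged from 162 in mouse 4 to 1227 in mouse 8. Among the 3 genes of the female biased list bright enough to test, Cyp2b13 ranged 13.5-fold, from 718 in mouse 6 to 9661 in mouse 5, and Cyp2b9 3.67-fold, from 2302 in mouse 6 to 8442 in mouse 5, and 2 of the 3 passed the F test over the list alone. The 5 male biased genes had a mean correlation of -0.001 (adjusted p = 0.510), and among them the carboxylesterase Ces3a ranged 6.54-fold, from 572 in mouse 6 to 3745 in mouse 3, and Gstp1 1.65-fold.

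Oxidative phosphorylation genes (39 tested) had a mean correlation of 0.553 (adjusted p = 0.000371) within a score range of 0.53, lowest in mouse 6 and highest in mouse 5. Cyc1 ranged 1.5-fold and Sdhd 2.31-fold, and 0 of the 39 had an unadjusted F test p under 0.05. With the first component removed their mean correlation was 0.169, and the call held. The 19 tested ribosomal protein genes had a mean correlation of 0.293 (adjusted p = 0.0169) within a score range of 0.35, and that call ended without mouse 5, which had their highest score (adjusted p = 0.282), with the stricter filter (0.0727, though the mean correlation was higher there, 0.404) and with the mean of all probe sets of a gene (0.101). With arrays scaled to a common median the mean correlation of the ribosomal protein genes was 0.522, and the call held. Gluconeogenesis and amino acid catabolism genes (11 tested, mean correlation 0.151, adjusted p = 0.375), urea cycle genes (8 tested, 0.256, adjusted p = 0.106) and xenobiotic metabolism genes (21 tested, 0.054, adjusted p = 0.626) did not vary together, though the urea cycle genes passed with the mean of all probe sets of a gene (adjusted p = 0.0122). Single members still ranged widely. G6pc, the last enzyme of glucose release, read 541 in mouse 2 and 4958 in mouse 5, Oat 4771 in mouse 6 and 13506 in mouse 4, and Gstm2 615 in mouse 5 and 2473 in mouse 6. Tdo2, Cps1 and Cyp2e1, the brightest members of these 3 lists, ranged 1.48-fold, 1.41-fold and 1.48-fold.

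Markers of other liver cells did not all follow the macrophage list. The 12 stellate cell and matrix genes had a mean correlation of 0.116 (adjusted p = 0.0535), with Col1a1, a fibrillar collagen gene, at 314 in mouse 5 and 969 in mouse 6. They passed without mouse 1, 7 or 8 (adjusted p = 0.0353, 0.0429 and 0.033), with the array sets as a block (0.0341) and with the mean of all probe sets of a gene (0.0425). The 10 hepatocyte genes had a mean correlation of 0.415 within a score range of 0.54 and did not pass (adjusted p = 0.0729), but passed without mouse 8 (0.0316), with no filter on brightness (0.0408) and with the first component removed (0.00631). Apob ranged 3.95-fold and the transcription factor gene Hnf4a 4.92-fold, from 266 in mouse 5 to 1308 in mouse 8. Lists with fewer than 5 tested genes are given as values. The B and plasma cell score (4 genes) ranged over 0.36 and its brightest gene Igha from 379 in mouse 8 to 921 in mouse 4. Endothelial genes (4 tested) had their lowest score in mouse 8 (-0.69) and their highest in mouse 4 (0.40), with Kdr at 139 and 512 in those mice. The erythrocyte score (4 genes) ranged over 0.58, lowest in mouse 8, with the globin Hba-a1 at 4393 in mouse 8 and 11685 in mouse 5. The neutrophil score (2 genes) was 1.48 in mouse 6 and at most 0.18 in the others. Its member S100a8 read 556 in mouse 6 and from 78.8 to 146 in the others. Cd24a, the only cholangiocyte gene bright enough to test, read 178 in mouse 5 and 359 in mouse 6. The exocrine pancreas (3 genes) and adipocyte (2 genes) scores ranged over 0.27 and 0.54, with Ctrb1 at 684 ± 65.0 and Car3 at 10199 ± 2407.

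Among growth, stress and clock genes, cell cycle genes had the lowest adjusted p against random lists (11 tested, mean correlation 0.415, adjusted p = 0.000371), with the highest score in mouse 6 (0.49) and the lowest in mouse 4 (-0.30). The replication helicase subunit Mcm5 read 145 in mouse 7 and 574 in mouse 6, and Stmn1 216 in mouse 3 and 552 in mouse 6. With the first component removed the mean correlation of the cell cycle genes was 0.267, and the call held. Circadian output genes had a mean correlation of 0.433 among 8 (adjusted p = 0.0039) and their lowest scores in mice 6 and 8 (-0.43 and -0.37). Dbp, a clock-driven transcription factor, ranged from 762 in mouse 6 to 2061 in mouse 2, and the call ended without mouse 6 (adjusted p = 0.0669) and with the first component removed (0.0986). The 2 tested genes of the Bmal1 arm, which peaks at the opposite time of day, had a score range of 0.36. The 5 fetal and tumour liver genes passed (mean correlation 0.387, adjusted p = 0.0388), and their Tff3, a trefoil peptide, ranged 26.1-fold from 53.7 in mouse 7 to 1402 in mouse 8. That call ended without mouse 2 (0.0746), with arrays scaled to a common median (0.0621, at a mean correlation of 0.333), with no filter (0.0565) and with the first component removed (0.237).

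Chaperone and immediate early genes varied together less clearly. The 10 heat shock chaperones had a mean correlation of 0.263 (adjusted p = 0.0373), and the call ended without mouse 3 or 7 (0.135 and 0.136), with arrays scaled to a common median (0.105), with no filter (0.0565), with the stricter filter (0.207) and with the first component removed (0.0986). The mean correlation was 0.426 with median scaling and 0.249 with the stricter filter, so those 2 settings ended the call without a large fall in it. The 8 immediate early genes had a mean correlation of 0.188 (adjusted p = 0.0494). Their call ended without mouse 1, 4, 5 or 6 (0.164, 0.0787, 0.0676 and 0.104), after quantile normalization (0.132) and median scaling (0.633), with the first component removed (0.0693), with the mean of all probe sets of a gene (0.0740) and with family probe sets left out (0.116). In some of these settings the mean correlation of the immediate early genes stayed close to 0.188 (0.184 without mouse 5, 0.171 without family probe sets and 0.199 with the first component removed). The chaperone gene Hspa1b read 176 in mouse 3 and 605 in mouse 7, and Dusp1, an immediate early phosphatase, 661 in mouse 4 and 1663 in mouse 1. Lists of p53 targets and senescence (8 tested, mean correlation 0.038, adjusted p = 0.375), ER chaperones (16 tested, 0.027, 0.376) and antioxidant genes (13 tested, -0.026, 0.763) did not pass. Their members Cdkn1a, a cell cycle inhibitor, and Hmox1, heme oxygenase, had their highest values in mouse 6 (544 and 3501).

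Of the 16 pairs of scores compared, 3 were related over the 8 mice after adjustment and 4 at an unadjusted p under 0.05. Interferon response and MHC class II scores rose together (r = 0.980, exact permutation p = 0.000273, adjusted p = 0.00218; rho = 0.905, adjusted exact p = 0.0243), with r = 0.974 without mice 6 and 8. Fatty acid synthesis and oxidation scores also rose together (r = 0.974, exact permutation p = 0.000149, adjusted p = 0.00218; rho = 0.952, adjusted exact p = 0.00913), with r = 0.867 without mice 6 and 8. The acute phase score rose with the macrophage score (r = 0.916, exact permutation p = 0.00159, adjusted p = 0.00847; rho = 0.952, adjusted exact p = 0.00913), with r = 0.768 without the same 2 mice. With the array sets as a block the 3 values of r were 0.985, 0.970 and 0.925, and a set of 4 mice is too small for a value of its own. Removal of the first principal component ended all 3 calls (r = 0.616, 0.772 and -0.183, adjusted exact permutation p = 0.212, 0.155 and 0.689). That component orders the mice much as the interferon score does, so this setting removes much of what the 3 pairs share and cannot test them.

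The stellate cell and macrophage scores had r = 0.741 (exact permutation p = 0.038) and did not pass after adjustment (0.152), with r = 0.579 without mice 3 and 6. No relation past adjustment was found between the female and male biased scores (r = 0.106, adjusted exact permutation p = 0.850, and r = -0.855 without mice 6 and 8), between growth hormone dependent and male biased genes (r = 0.110, 0.847, and r = -0.122 without mice 1 and 2), between sterol and fatty acid synthesis (r = 0.356, 0.629, and r = -0.659 without mice 4 and 6) or between sterol synthesis and bile acid genes (r = 0.561, 0.329, and r = 0.165 without mice 4 and 6). The remaining pairs had r of 0.509 for fatty acid oxidation with gluconeogenesis (0.344 without mice 6 and 8), -0.591 for acute phase with xenobiotic metabolism (0.276 without mice 6 and 8), -0.307 for B cells with T cells (-0.278 without mice 1 and 4), 0.117 for circadian output with the Bmal1 arm (0.112 without mice 6 and 8), and 0.433 for ER with heat shock chaperones (0.992 without mice 5 and 8). For oxidative phosphorylation with ribosomal proteins r was 0.561 (0.924 without mice 6 and 8), for immediate early with circadian output -0.205 (-0.408 without mice 1 and 4), and for gluconeogenesis with circadian output 0.202 (0.759 without mice 2 and 5), and none of these passed. The pair of chaperone lists passed without mouse 5 (r = 0.892, adjusted exact permutation p = 0.0317), and oxidative phosphorylation with ribosomal proteins passed with arrays scaled to a common median (r = 0.825, 0.0325). The female and male biased scores passed with the first component removed (r = 0.922, 0.0111), and fatty acid oxidation with gluconeogenesis passed with members scaled to an SD of 1 (r = 0.879, 0.0116).

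**Figure D3:**
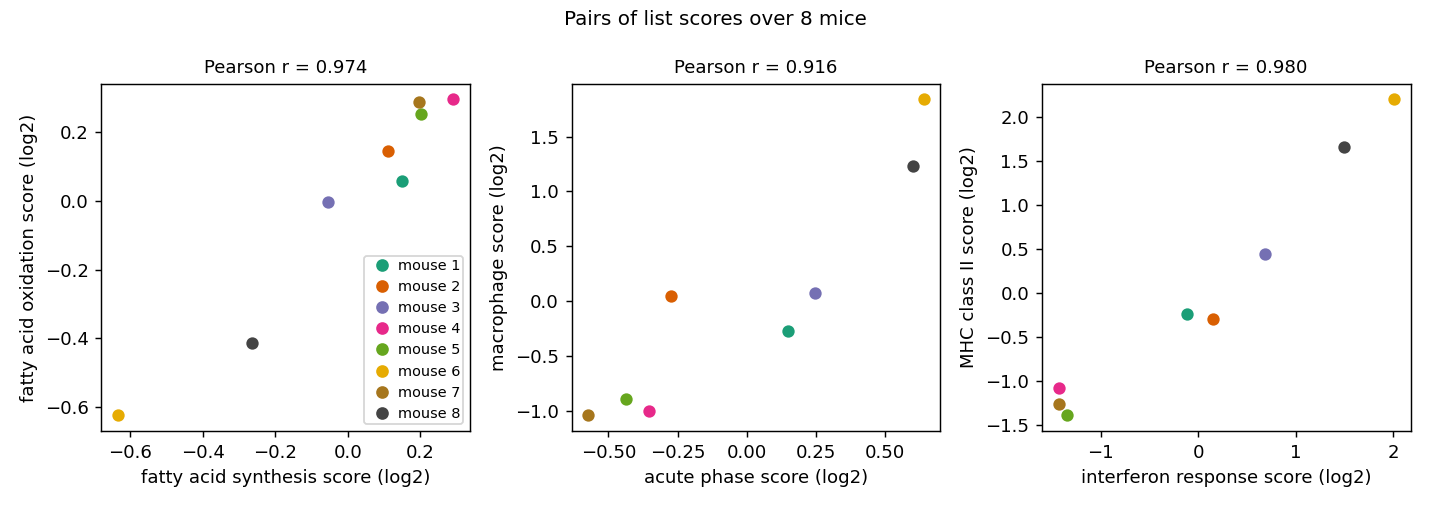
List scores (log2 scale) of the 3 pairs that passed, plotted against each other with 1 coloured point per mouse and Pearson's r above each panel. Mice 6 and 8 lie lowest in both fatty acid scores and highest in the other 4 scores.

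Arrays correlated with each other over the tested probe sets at a median r of 0.945, from 0.881 for mice 5 and 6 to 0.977 for mice 4 and 7, and 0 of the 28 pairs held identical values. These correlations are across genes, which are not independent replicates. The array of mouse 5 had a 3' over 5' ratio of the Gapdh control probe sets of 1.41 on the log2 scale, against -0.33 to 0.09 on the other 7, and a ratio for pyruvate carboxylase (Pcx) of 5.35 against 1.4 to 3.20. Such ratios rise when RNA is shortened from its 5' end. Its ratios for Actb (0.67) and Tfrc (2.28) lay within those of the other arrays. The 3' control of Actb read 763 in mouse 5 and 12065 in mouse 8. Its 3' over 5' ratio varied less, from 0.536 in mouse 8 to 0.999 in mouse 3 on the log2 scale. An Actb probe set outside the controls ran only from 1430 in mouse 7 to 2227 in mouse 6. A further Actb probe set was lowest in mouse 5 (366, with the next lowest 909 in mouse 7). Mouse 5 held the lowest value of Xist, Hnf4a, Pdia3 and Plk1, among other genes, and the highest ribosomal protein and oxidative phosphorylation scores. Levels of 9 hybridization control probe sets, averaged relative to their means, were 1.15 to 1.27 on the arrays of mice 1 to 4 and 0.756 to 0.854 on those of mice 5 to 8.

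**Figure D4:**
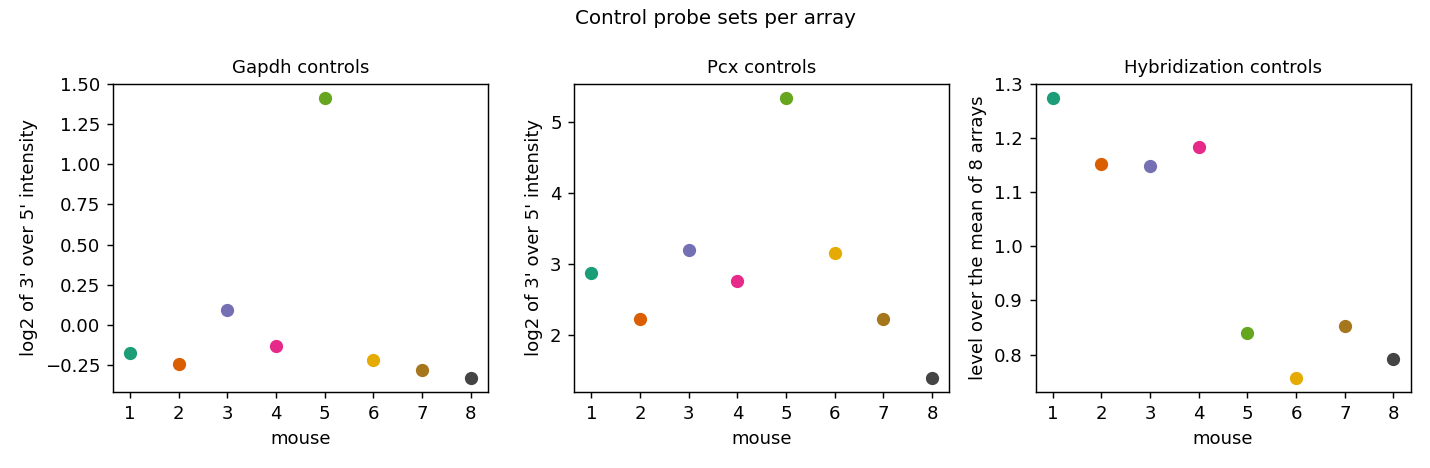
Control probe sets on the array of each mouse, with the log2 ratio of 3' over 5' intensity for Gapdh and for Pcx, and the level of 9 hybridization controls over their mean of the 8 arrays. Mouse 5 stands at 1.41 for Gapdh and 5.35 for Pcx, and the hybridization controls separate mice 1 to 4 from mice 5 to 8.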

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

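All tests in this part were chosen after the result was seen, except the share of mouse 5's genes with a low value and the correlation after quantile normalization, whose outcomes were set beforehand. A mouse was called apart where its gap to the nearest other mouse exceeded Dixon's critical value as a share of the range. Checked were 114 genes, 36 list scores, 4 array measures and the probe sets of the label check genes, and 23 results met this. Chance sets about 1 in 20 apart, but the count cannot be set against that, because 6 of the genes were named since 1 mouse stood apart in them (all mouse 5) and 12 since none did. Over all tested genes 423 of 4869 (8.69%) had 1 mouse apart. No biological explanation was tested, since the design gives 1 group, beyond the cell makeup of the samples, which was compared between mice.

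The array of mouse 5 stood apart by its Gapdh ratio (a gap of 0.756 of the range) and its Pcx ratio (0.544), and by low values of Xist (0.547), Hnf4a (0.610), Plk1 (0.604), Pdia3 (0.537), Scx (0.696), Coro1a (0.548), Qsox1 (0.575), Cd99 (0.685) and Sprr2j-ps (0.549), while Tdo2 was high (0.527). Scx, Coro1a, Qsox1, Cd99 and Sprr2j-ps were named because 1 mouse stood apart, so their gaps follow from that choice, while Xist was also a label check gene. Shortened RNA may account for the pattern, since its Gapdh ratio lay 1.32 and its Pcx ratio 2.15 on the log2 scale above the highest of the other arrays, but its Actb and Tfrc ratios lay inside their range, a comparison added afterwards. The level of the Actb 3' control did not follow that of another Actb probe set over the arrays. That difference in level alone does not set the Actb ratio aside, and its source was not tested. Of the 216 genes with mouse 5 alone apart 154 (71.3%) were lowest there, past the 70% set beforehand as a sign of truncation, yet 136 of 207 genes (65.7%) with another mouse apart were also low (one-sided Fisher's exact p = 0.128), and this comparison, added after the result, led to RNA truncation being left open where it had first been counted as met. The hybridization controls of mouse 5 lay 4.77% above the mean of the rest of its array set. That cannot decide on the array set as a source, because the sets were drawn from these same controls.

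The interferon response score separated the mice over a range of 3.44 on the log2 scale. An array set effect is argued against, since the SD within array sets was 1.07 times that over all mice. RNA truncation is argued against by mice 4 and 7, which scored -1.43 each with Gapdh ratios of -0.13 and -0.28. Mouse 5, the only array with a raised Gapdh ratio (1.41), scored -1.34, also at the low end. The rho between the score and the Gapdh ratio was -0.190, which says little where only mouse 5 had a raised ratio. Blood in the sample is argued against by the slope of the erythrocyte score on the interferon score, -0.145 (at most -0.130 with any mouse left out), but lymphoid tissue stays open, since the B and plasma cell slope was -0.0378 and the T and NK cell score rose with a slope of about 1, carried by Ccl5 (1.74, at the floor in 4 mice) and Ltb (1.03) more than by Cd4 (0.23). Macrophage and endothelial markers (4 genes for the latter) moved apart, with a difference in slope of 0.943 (at least 0.857 with any mouse left out). That argues against a lower share of hepatocytes in which both other cell types rise alike. It cannot decide on a lower share through added immune cells, because endothelial markers need not rise then. A change in the number of macrophages or T cells and disease of old mice stay open and were not tested.

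Fatty acid oxidation scores were lower in mice with higher interferon scores (r = -0.941 over the 8 mice). Scaling between arrays is argued against, since the correlation was -0.948 after quantile normalization. The slope of the hepatocyte score on the interferon score exceeded that of the fatty acid oxidation score by 0.226 (at least 0.216 with any mouse left out). That argues against a lower share of hepatocytes only as far as the hepatocyte score follows that share. Its r with the interferon score was -0.113 over the 8 mice and 0.795 without mice 6 and 8. Alb, a member, was the brightest probe set on the arrays of mice 1, 2, 5 and 7, and whether such bright probe sets respond fully was not tested. What links the scores stays open.

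In mouse 6 the neutrophil score was high (a gap of 0.667 of the range), with S100a8 (0.685), and the thyroid hormone responsive score (0.562) and the bile acid score (0.646) were low. These last scores are not independent, since both lists hold Cyp7a1, which was lowest in mouse 6. Col3a1 (0.553), Dlk1 (0.644) and Cyp4a12b (0.544) were also high in mouse 6. In mouse 3 Hp (0.565) and Asl (0.735) were high, and the dimmer of 2 probe sets of Ghr (0.636) was low. Igfbp3 was low in mouse 8, at 56.3 (0.833).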

How the results depend on the processing

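The chi-square test, the block of array sets and the runs without family probe sets were chosen after the data were seen. The F test called 0 probe sets under every setting run, with 250 to 437 at an unadjusted p under 0.05, and the chi-square test called 1147, from 648 with the stricter filter and 896 with the first component removed to 2294 with no filter. Lists over-represented among genes marked by the chi-square test numbered 7, 11 with no filter, 10 with the stricter filter, 9 with median scaling or no trend, 4 with the first component removed, 6 with the array sets as a block, and 5 to 7 with each mouse left out. Lists whose members varied together numbered 9 with arrays scaled to a common median and 8 with the stricter filter, all of them among the 15, and 8 with the first principal component removed, 7 of them among the 15. With each mouse left out they numbered 9 (without mouse 6) to 17 (without mouse 8). Pairs past adjustment numbered 1 with the first component removed and 3 to 4 with each mouse left out, and the median correlation between arrays was 0.938 to 0.951. The interferon response, macrophage, sterol synthesis, oxidative phosphorylation and cell cycle lists passed in every alternative in which they were run, but with the first component removed the mean correlations of the interferon, macrophage, oxidative phosphorylation and cell cycle lists were lower (0.410, 0.317, 0.169 and 0.267). Removing the first component takes out much of the interferon pattern itself, so calls lost there cannot tell whether that pattern is sound. The cause was not tested for any change given here. No paired analysis was possible because the labels give 1 group.

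A change of side means a list's mean correlation on the other side of the random median, or a pair's r of the other sign. With arrays scaled to a common median this held for the male biased (-0.0806), acute phase (0.151), p53 (0.0258) and ER chaperone (0.00257) lists and for growth hormone dependent with male biased genes (-0.0814). With no filter it held for the male biased (-0.0979) and xenobiotic (0.0415) lists, B with T cells (0.225) and circadian output with the Bmal1 arm (-0.418), and with the stricter filter for immediate early with circadian output (0.426). With the first component removed it held for fatty acid oxidation (-0.0147), xenobiotic (0.0841) and antioxidant (0.0101) lists. In that setting the pairs were fatty acid oxidation with gluconeogenesis (-0.446), acute phase with xenobiotic metabolism (0.264) and with macrophage (-0.183), B with T cells (0.197), circadian output with the Bmal1 arm (-0.285), stellate with macrophage (-0.298), immediate early with circadian output (0.336) and gluconeogenesis with circadian output (-0.674). Growth hormone dependent with male biased genes changed sign with the mean of all probe sets (-0.0837), the median over members (-0.652) and members scaled to an SD of 1 (-0.0952). Female with male biased genes did so with the median over members (-0.332), the block (-0.156) and family probe sets left out (-0.0136). The male biased list changed side with the block (-0.0210) and with family probe sets left out (-0.0285), as did the growth hormone dependent list in the latter (-0.00774).

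With each mouse left out, mean correlations ran from -0.0988 to 0.000269 for growth hormone dependent, -0.0541 to 0.0377 for male biased and -0.0869 to 0.161 for bile acid genes. Values of r ran from -0.0862 to 0.518 for sterol with fatty acid synthesis, -0.661 to 0.377 for female with male biased, -0.0618 to 0.359 for growth hormone dependent with male biased, -0.559 to 0.148 for immediate early with circadian output, and -0.361 to 0.591 for circadian output with the Bmal1 arm. The number of arrays and the floor of 37.2 limit what dim genes can show, and 67 of 50120 tested values lay at the floor.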

Other observations

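All relations in this part were chosen after the interferon scores were seen. Among 4852 genes outside that list, 153 rose and 85 fell with the score over the 8 mice (adjusted exact permutation p under 0.05). Without mice 6 and 8, 210 of these 238 kept their sign and an r over 0.7 in size. That count is no independent check, because the 238 were chosen by r over mice that include the remaining ones. Beside the MHC class II genes (8 of 8 rose) and macrophage markers (10 of 14), the rising genes held Ccr2, the receptor that draws monocytes into tissue (r = 0.939, from under the floor to 1022), Acod1, the enzyme that makes itaconate (r = 0.894, from under the floor to 1227), and the adhesion gene Icam1 (r = 0.943, 105 to 1028). Falling genes held Cyp4a14 (r = -0.917), the retinol saturase gene Retsat (r = -0.961, 1001 to 4253) and the carboxylesterase gene Ces1d (r = -0.891). They also held the female biased Cyp2b13 (r = -0.861) and Hamp, the iron hormone hepcidin (r = -0.890, 10696 to 24152). Without mice 6 and 8 r was -0.636 for Cyp2b13 and -0.649 for Hamp. Of the 238, 193 were in none of the fixed lists. The falling genes held 5 of the 20 fatty acid oxidation genes, and of the 23 acute phase genes 4 rose and 1, Hamp, fell.

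Each of the other list scores was set against the interferon score, with adjustment over all of them. This includes lists with fewer than 5 tested genes, whose scores rest on few genes. The macrophage (r = 0.976, rho = 1, adjusted exact permutation p = 0.000868), T and NK cell (r = 0.938, rho = 0.929, 0.00521), acute phase (r = 0.943, rho = 0.952, 0.00521) and p53 (r = 0.912, rho = 0.905, 0.0113) scores rose with it. Of single genes 1 of the 3 in the T and NK cell list rose by its own test (Ltb, with r = 0.490 for Cd4), and 1 of the 8 in the p53 list (Cdkn1a, with r = -0.807 for Perp), whose members did not vary together (mean correlation 0.038). The fatty acid synthesis (r = -0.916, rho = -0.929, adjusted exact permutation p = 0.00174) and oxidation (r = -0.941, rho = -0.952, 0.00231) scores fell. Without mice 6 and 8 the r of these 6 scores were 0.984, 0.861, 0.843, 0.755, -0.889 and -0.947, and with the array sets as a block 0.987, 0.937, 0.942, 0.933, -0.956 and -0.971. The female biased (3 genes, r = -0.850, 0.00595), oxidative phosphorylation (r = -0.871, 0.0180) and erythrocyte (4 genes, r = -0.816, 0.0493) scores passed by r but not by rho (adjusted exact permutation p = 0.0977, 0.0953 and 0.0977). Their r without mice 6 and 8 were -0.710, -0.586 and -0.628. Antioxidant (r = 0.794, 0.0321), neutrophil (2 genes, r = 0.736), cholangiocyte (1 gene, Cd24a, r = 0.806) and fetal liver (r = 0.850, adjusted exact permutation p = 0.0305 each for the last 3) scores also passed by r alone, and without mice 6 and 8 their r were 0.192, 0.487, 0.302 and 0.553. The hepatocyte score had r = -0.113 (0.795 without mice 6 and 8, 0.223 after quantile normalization and -0.455 with median scaling) and did not pass.

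Noise of single probe sets was tested as a source of the genes marked by the chi-square test, with outcomes set beforehand (a median correlation between probe sets of 1 gene of at most 0.3 if noise, over 0.5 if not). The median was 0.381 for the marked genes and 0.188 for the others, which decided neither way.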
